A study of Hordeum vulgare with 18 samples.

How the data were processed

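Small RNAs of barley shoots were sequenced in 18 libraries, 3 for each of 3 durations (1, 3 and 6 h) at 35.5 °C and at 21 °C. Groups were taken from the labels, as were lanes, with heat and control at 1 h and heat at 3 h on lane 1 and the other groups on lane 2. The replicate numbers follow the order of the samples, and whether heat and control plants were paired is not given in the sources used here.

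Per the file headers, the authors counted each distinct sequence and annotated it against plant miRNA precursors. The deposited counts are whole reads per sequence and library. The deposited normalized values are RPM per the file headers, and in each library they equal the count times 1 constant, from which the library totals of 23280481 to 44219180 were computed. Per the file headers the authors compared heat and control with an "EDGE" test with tagwise dispersions and give a p-value with its FDR correction. The authors' fold column is a signed linear score, per the file headers, negative where heat is lower. Tool names, versions and the annotation release are not given in the sources used here. The tables hold sequences of 18 to 25 nt from precursors of 26 species, all matched with 0 mismatches, and 1 line of the 1 h table without content was left out. A sequence with no read in a table's libraries is not listed there. No genome was used, so no coordinates are given. Near-identical families (miR165, miR166 and miR5168; miR156 and miR157; miR159 and miR319) share sequence, so the split of reads between them follows the authors' annotation and is uncertain.

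Counts per sequence were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test with TMM factors, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment, and calls are at an adjusted p under 0.05. Each duration was fitted on its own 6 libraries. Family totals were summed over all sequences of a numbered family and tested with the library sizes and factors of the whole table. CPM are counts divided by the table total times the TMM factor, which ran from 0.815 to 1.27, so they are relative to the annotated sequences of 1 table and are not set across times. The 2720 sequences in all 3 tables (of 7252 in any), which hold 99.95 to 99.96% of the counts, went into 1 fit of the 18 libraries for the average heat effect, the effect at 6 h minus that at 1 h, and time contrasts within a lane. The tests, samples and lists, the rule for naming and the alternatives were fixed before the data were examined, except for those said to be added. Shares of counts by length (20 to 24 nt) and by annotation were compared with exact two-sided permutation tests (scipy 1.17.1), adjusted over 15 and 9 tests. With 3 libraries against 3 the smallest p of such a test is 0.1. Replicates were compared pairwise, with r from 0.907 to 0.972 on log2 CPM and a chi-square per degree of freedom of 18.4 to 423, so none were copies of each other. Other software was limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

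The text names, per duration, each called family, the 5 called sequences with the largest rise and the 5 with the largest fall that had a mean of at least 10 CPM and no overlap of ranges, the most abundant members of each list, miR160, miR166, miR167 and miR5175, which earlier work named as heat responsive in barley, and the most abundant sequence. Lists were the families of earlier barley heat work; copper (miR397, miR398, miR408, miR528, miR857); phosphate and sulfate (miR395, miR399, miR827); auxin (miR160, miR164, miR167, miR390, miR393); phase change (miR156, miR157, miR172); leaf development (miR159, miR165, miR166, miR319, miR396); NF-YA and GRAS regulators (miR169, miR171); silencing (miR162, miR168, miR403); 20 cereal families; and sequences of 21, 22 and 24 nt. The lists share miR160, miR166, miR167, miR5175, miR528 and miR827. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over 12 lists. None of the camera calls held with the estimated correlation. Median, mean and camera direction differed in sign for the 21 nt list at 1 h (0.02, -0.05, down), the 22 nt and 24 nt lists at 3 h (0.02, -0.03, up; -0.07, -0.13, up), and the copper and 22 nt lists at 6 h (0.02, -0.11, down; -0.01, -0.04, up). A list of reproductive phased-RNA triggers (miR2118, miR2275, miR482) had 0 tested sequences: miR2275 had 10 counts in heat and 4 in control at 1 h, 0 and 1 at 3 h and 8 and 2 at 6 h, miR2118 had 2 and 0 at 3 h, and miR482 had 0. Lists of tRNA, rRNA, snoRNA and snRNA, heat shock mRNA, photosynthesis mRNA and organelle fragments had 0 members in these miRNA tables.

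Alternatives were DESeq2, RLE factors, library size scaling, no filter, a filter of 10 CPM in 3 libraries, a log2 fold change of at least 1, 1 fit of all 18 libraries, leaving out each library in turn, and, for shares, leaving out the 10 most abundant sequences. Added after seeing the data were scaling by the implied library totals, leaving out each library for the average effect, leaving out both libraries that stood apart on the first principal component, and the 6 h minus 1 h contrast per family with its alternatives.

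The sequence and family fits were tested on simulated counts drawn from the fitted means, dispersions and library sizes of each comparison, 10 times each. Of sequences changed 2-fold, 32.6, 22.5 and 47.2% were recovered at 1, 3 and 6 h, and of those changed 4-fold, 90.5, 84.2 and 90.2%, with 3.7, 4 and 3.6% of calls false. For families the 2-fold shares were 55.7, 35.4 and 47.5%, the 4-fold shares 97, 91.6 and 95.9% and the false calls 5.1, 9.6 and 5.4%. For the average effect 65.2 and 97.4% of sequences and 88.8 and 100% of families were recovered at 2-fold and 4-fold (3.9 and 8.9% false), and for the 6 h minus 1 h contrast 5.2 and 38.7% of sequences and 19 and 66% of families (3.5 and 5.7% false). In a simulation of lists, camera with the preset correlation put 0 of 20 unchanged lists under 0.05 and fry 4 of 20. Its counts were drawn for each sequence independently. In the real libraries sequences of a list can be correlated, with an estimate of 0.554 for the phosphate and sulfate list at 1 h. The simulation therefore cannot show how often camera calls unchanged lists in these libraries.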

Results

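Small RNAs were sequenced from the shoots of 2-week-old plants of a spring line of barley, a cereal crop, that had spent 1, 3 or 6 h at 35.5 °C or had stayed at the control temperature of 21 °C. The 6 groups of 1 temperature and 1 duration each held 3 libraries, which the labels call biological replicates. Each duration had its own table of sequences that match known plant microRNA (miRNA) precursors exactly. They held 4750 sequences of 170 families at 1 h, 4671 of 174 at 3 h and 4603 of 186 at 6 h. A miRNA is a short RNA that guides the silencing of matching mRNAs. Each library held 1449374 to 3214221 counts in its table, which was 5.11 to 9.02% of the library total implied by the deposited RPM values. The floor of 3 counts lay between 0.0678 and 0.129 RPM, and it covers counting error only. The most abundant sequence took 23.98 to 35.03% of a library's counts, and the 10 most abundant took 77.4 to 84.7%. Heat and control libraries of 1 h shared a sequencing lane, as did those of 6 h, while at 3 h all heat libraries were on lane 1 and all control libraries on lane 2. The library titles also carry a different library prefix on each lane. What the prefix stands for is not given in the sources used here, so it cannot be told apart from lane. On the first principal component of family levels (27.7% of the variance), control 3 h replicate 1 at 6.68 and heat 6 h replicate 2 at 6.18 lay apart from the other libraries, which ranged from -3.86 to 1.07. Fold changes are log2 values of heat over control with their SE, levels are scaled CPM with their SD, and n = 3 libraries per group throughout.

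The comparison at 1 h asks which miRNA sequences respond to a short exposure. The clearest change was in precursor sequences of miR444, a grass family whose mature miRNAs target mRNAs of MADS-box transcription factors. The MIR444c precursor sequence CGGCAAGCTAGAGACAGCAAC, singled out after its values were seen, fell from 18935 ± 437 CPM in control to 5617 ± 736 CPM in heat (-1.75 ± 0.22, adjusted p = 0.00144). Its shorter forms GGCAAGCTAGAGACAGCAAC (-1.78 ± 0.22, adjusted p = 0.00144) and GCAAGCTAGAGACAGCAAC (-2.002 ± 0.27, adjusted p = 0.00151) fell with it. The log2 ratio of the first of these MIR444c sequences to a mature sequence of MIR444b and MIR444c was also compared. It differed between heat and control by -1.21 at 1 h, -1.04 at 3 h and -1.22 at 6 h. That mature sequence thus did not fall as far as the precursor sequence. The fall of the precursor sequence is therefore not a measure of the miRNA that targets MADS-box mRNAs. Other miR444 sequences rose. The MIR444b mature 3′ sequence TGCAGTTGCTGCCTCAAGCTT went from 61.9 ± 10.4 to 167 ± 7.89 CPM (1.43 ± 0.24, adjusted p = 0.00758). TGCAAGTCGTGCAGTTGCTGC of MIR444a rose from 4.20 ± 0.272 to 23.2 ± 7.72 CPM (2.45 ± 0.42, adjusted p = 0.00767) and GCATGAGGCAACAACTGC of MIR444b from 1.26 ± 1.48 to 22.8 ± 9.48 CPM (4.06 ± 0.73, adjusted p = 0.00897). The calls of these rises were lost in 1, 1 and 2 of 13 alternatives. Precursor sequences of MIR169c, whose family targets NF-YA transcription factor mRNAs, fell as well, with CCTAGTTCTCTTCTTCTGGT at -3.48 ± 0.45 (adjusted p = 0.00144) and CCTAGTTCTCTTCTTCTGGTG at -2.41 ± 0.35 (adjusted p = 0.00255).

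In total 13 of 740 tested sequences passed at 1 h, 4 higher and 9 lower. By annotation 12 of the 13 were precursor sequences and 1 a mature arm. The precursor annotation can include end variants of a mature arm. Targets given in the text are those known for a family and were not assigned to single sequences. Of the 13 calls, 8 of 44 belonged to miR444 (4 higher, 4 lower) and 3 of 78 to miR169. The rest were GAATGACGCCGGGTCCGAAAG of MIR166b, which fell from 209 ± 28.8 to 51.3 ± 22.7 CPM (-2.02 ± 0.32, adjusted p = 0.00482), and AGCTGCCGACTCATTCATCC of MIR319a and MIR319b, named after its values were seen, which fell by 4.26 ± 0.86 on the log2 scale (adjusted p = 0.0192). Heat and control ranges did not overlap for 16.6% of sequences, where chance gives 10%. No family total passed with edgeR among 75 tested, with 6 under an unadjusted p of 0.05 and 2 called by DESeq2, miR444 and miR5200. The miR444 total was 19269 ± 3141 CPM in heat and 36919.6 ± 1830 in control (-0.94 ± 0.19, adjusted p = 0.0596), lower in each heat library than in any control. The commonest sequence, TTCGGACCAGGCTTCATTCCC of MIR166, stood at 263851 ± 63479 against 243371 ± 16114 CPM (0.12 ± 0.25, adjusted p = 0.93), and its sign turned with implied totals and without heat 1 h replicate 3.

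Of the families that earlier work named as heat responsive in barley, none passed at 1 h. miR160 and miR167, which target auxin response factor mRNAs, stood at 0.26 ± 0.19 (adjusted p = 0.558) and -0.24 ± 0.25 (adjusted p = 0.736). miR166, which targets HD-ZIP III mRNAs, stood at 0.11 ± 0.20 (adjusted p = 0.812), with its sign turned by DESeq2, by implied totals and without heat 1 h replicate 3. miR5175 had 5 counts in heat and 0 in control, too few to test. Of the 119 sequences of this list 1 passed, the MIR166b sequence above (also 1 adjusted over the list alone). Among 132 sequences of cereal families 4 rose and 4 fell, all miR444 (4 and 5 adjusted over the list alone, the added one being CCTGTGCCTGCCTCTTCCATT of MIR528). In that list miR5048 stood at -0.02 ± 0.31 and miR5051 at -1.50 ± 0.80. The list of NF-YA and GRAS regulators had 3 of 92 lower, the MIR169c pair and CGGGATGCAGCCAAGGATGAC of MIR169d, as many adjusted over the list alone. The family totals stood at -0.17 ± 0.19 for miR169 and -0.09 ± 0.21 for miR171. The leaf development list had 2 of 194 lower, those of MIR166b and MIR319, as many adjusted over the list alone. Its family miR396 stood at -0.04 ± 0.16, miR159 at 0.35 ± 0.40 and miR319 at 0.30 ± 0.20.

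None of the 32 sequences of copper-related families passed with edgeR at 1 h, nor adjusted over the list alone, with 2 under an unadjusted p of 0.05 and 1 called by DESeq2. The families miR408, miR397, miR528 and miR398 stood at 0.11 ± 0.31, 0.13 ± 0.26, -0.65 ± 0.39 and 0.37 ± 0.22. The phosphate and sulfate list had 0 of 13, 0 adjusted over the list alone, 0 unadjusted and 0 by DESeq2, with miR827 at -0.45 ± 0.33, miR399 at 0.22 ± 0.37 and miR395 at 0.72 ± 0.42. The auxin list had 0 of 75 with edgeR (0 adjusted over the list alone, 7 unadjusted, 0 by DESeq2), with miR393 at 0.05 ± 0.19 and miR390 at 0.44 ± 0.22. The phase change list had 0 of 46 (0 adjusted over the list alone, 2 unadjusted, 0 by DESeq2), with miR156 at 0.18 ± 0.25 and miR172 at -0.57 ± 0.28. The silencing list had 0 of 28 with edgeR, 7 unadjusted and 3 by DESeq2, but 2 higher and 2 lower adjusted over the list alone. All were forms of miR168, which targets an ARGONAUTE mRNA, with CCCGCCTTGCACCAAGTGA and CCCGCCTTGCACCAAGTGAA higher and CGCTTGGTGCAGATCGGGAC and CGGGCTCGCTTGGTGCAGATC lower. Of the length lists, the 21 nt sequences had 2 higher and 4 lower of 258, as many adjusted over the list alone. The 22 nt and 24 nt sequences had 0 of 97 and 0 of 35 over all and adjusted over the list alone, with 6 and 3 unadjusted and 1 and 0 by DESeq2. No list as a whole passed camera, whose lowest adjusted p was 0.0653 for the NF-YA and GRAS regulators (0.932 with an estimated correlation), and fry called 0. Without heat 1 h replicate 2 the count of called sequences was 23, and it was 23 with DESeq2 and 28 with no filter on low counts. The miR444 family passed in the fit of all 18 libraries, with DESeq2, with RLE factors, with implied totals and without heat 1 h replicate 1, while miR5051 passed without heat 1 h replicate 2.

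At 3 h heat and control libraries lay on different lanes, so the values of this time taken alone carry the lane with the temperature. A pair of families fell. miR528, a grass family with targets among copper protein mRNAs, went from 248 ± 16.9 CPM in control to 89.7 ± 4.71 CPM in heat (-1.46 ± 0.14, adjusted p = 0.0029). In the fit of all 18 libraries its control level at 6 h minus 3 h was -1.41 ± 0.41 (edgeR adjusted p = 0.265). Its heat level at 3 h minus 1 h was -0.17 ± 0.41. Each of these contrasts lay within 1 lane. Whether a high control at 3 h sets the difference was not tested. miR444 went from 39370.4 ± 1435 to 18412 ± 1261 CPM (-1.10 ± 0.12, adjusted p = 0.0029), again with CGGCAAGCTAGAGACAGCAAC lower (-1.87 ± 0.22, adjusted p = 0.00256; named after its values were seen). Both totals were lower in each heat library than in any control. The mature 5′ sequence CAGGGATGGAGCAGAGCAAGG of miR408, a family with copper protein targets such as plantacyanins, fell from 215 ± 52.0 to 22.6 ± 4.83 CPM (-3.25 ± 0.33, adjusted p = 0.00233). The targets are those of the family and were not assigned to this arm.

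In all 31 of 713 sequences passed at 3 h, 7 higher and 24 lower, in 13 families. By annotation 26 of the 31 were precursor sequences and 5 mature arms. The largest rise was of CAGGCTTTCTTGAACTGTC of MIR396a and MIR396b, whose family targets growth-regulating factor mRNAs, from 0.741 ± 0.872 to 27.8 ± 6.58 CPM (5.08 ± 0.68, adjusted p = 0.00313; 5 and 183 counts). CTTGGACTGAAGGGTGCTCC of MIR319b (2.70 ± 0.54), TGCTGTTGCGTGCTCACCCT of MIR156e (2.31 ± 0.48), CTCCCTGAATGCCATCCGAG of MIR160f (2.10 ± 0.41) and GGAATGTTGTCTGGTTCAAG of MIR166a (1.92 ± 0.44) followed, with adjusted p from 0.0233 to 0.0422. Their calls were lost in 3, 4, 4 and 5 of 13 alternatives. The deepest falls, beside that of the MIR408 sequence above, were of ACCGGCGCTGCACGCAATGACG of MIR397a (-4.35 ± 0.56), CCTAGTTCTCTTCTTCTGGT (-4.004 ± 0.50) and CCTAGTTCTCTTCTTCTGGTG (-3.13 ± 0.39) of MIR169c, and AGCTGCCGACTCATTCATCCA of MIR319a and MIR319b (-3.52 ± 0.57, adjusted p = 0.00986). Ranges did not overlap for 25.9% of sequences against 10% by chance. Among families, 15 of 76 were under an unadjusted p of 0.05, and DESeq2 called 5, adding miR408, miR5083 and miR5200. TTCGGACCAGGCTTCATTCCC stood at 306203 ± 4576 against 281481 ± 16857 CPM (0.12 ± 0.16, adjusted p = 0.697), with its sign turned under library size scaling.

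Among 31 sequences of copper-related families 6 fell and 0 rose at 3 h (11 lower adjusted over the list alone), 3 of them of miR408, 2 of miR397 and 1, CCTGTGCCTGCCTCTTCCATT, of miR528 (-2.81 ± 0.34, adjusted p = 0.00256). Of the 4 families miR528 fell (also miR408 adjusted over the list alone), with miR408 at -0.96 ± 0.21 (adjusted p = 0.0882), miR397 at -0.25 ± 0.19 and miR398 at -0.43 ± 0.39. As a whole the list was lower than the other sequences by camera (adjusted p = 1.04e-07, and adjusted p = 0.12 with an estimated correlation) and moved lower by fry (adjusted p = 0.00574). The phosphate and sulfate list had 1 of 13 lower, GTGCAGTTCTCCTCTGGCATG of MIR399a (-2.37 ± 0.47), named after its values were seen. Adjusted over the list alone 3 were lower, the others being the MIR827 sequences TTTTGTTGGTTGTCATCT and TTTTGTTGGTTGTCATCTAACC. Its camera adjusted p was 0.0116 (adjusted p = 0.459 with an estimated correlation), and miR827, miR399 and miR395 stood at -1.20 ± 0.41, -0.93 ± 0.38 and 0.14 ± 0.45. The list of NF-YA and GRAS regulators had 6 of 95 lower, all miR169, and as many adjusted over the list alone (camera adjusted p = 3.42e-06, and adjusted p = 0.431 with an estimated correlation). The family totals stood at -0.61 ± 0.24 for miR169 and -0.65 ± 0.27 for miR171. Among 182 sequences of the leaf development list 5 rose and 4 fell, as many adjusted over the list alone. The list was higher than the other sequences by camera (adjusted p = 7.8e-08, and adjusted p = 0.199 with an estimated correlation). Its families miR166, miR396, miR159 and miR319 stood at 0.12 ± 0.07, 0.66 ± 0.29, 1.13 ± 0.74 and 0.46 ± 0.19. The remaining family, miR165, stood at -0.19 ± 0.52. In control 3 h replicate 1 miR159 stood at 9327 CPM and miR396 at 132615. The other controls held 68186 and 63836 CPM of miR159 and 280753 and 241127 of miR396. No list was tested without that library. Fry called neither the leaf development list nor that of NF-YA and GRAS regulators (each adjusted p = 0.0939), nor the phosphate and sulfate list (adjusted p = 0.183).

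The cereal list at 3 h had 6 of 121 lower, 5 of miR444 and 1 of miR528 (1 higher, TGCAGTTGCTGCCTCAAGCTT, and 6 lower adjusted over the list alone). Of its 16 families 2 were lower by both counts, with miR5048 at 0.80 ± 0.49 and miR5051 at 0.36 ± 0.22. It moved lower by fry (adjusted p = 0.0314) and was not called by camera (adjusted p = 0.132). The earlier barley heat families were not called. miR160 at 0.01 ± 0.32 (adjusted p = 0.978), miR166 at 0.12 ± 0.07 (adjusted p = 0.355) and miR167 at 0.11 ± 0.12 (adjusted p = 0.605) all turned negative under library size scaling, and miR160 also without heat 3 h replicate 1 or 2 or control 3 h replicate 2 or 3. miR5175 had 5 and 0 counts. Of their 113 sequences 3 rose and 2 fell, as many adjusted over the list alone. They were CTCCCTGAATGCCATCCGAG, GGAATGTTGTCTGGTTCAAG and GGAATGTTGTCTGGCTCGGG higher and GAATGACGCCGGGTCCGAAAG and GGAACGTTGGCTGGCTCGAGG lower. The auxin list had 1 of 73 higher and the phase change list 1 of 48 higher, the MIR160f and MIR156e sequences above, each also adjusted over the list alone. miR393 stood at -0.45 ± 0.25, miR390 at -0.26 ± 0.25, miR156 at 0.02 ± 0.14 and miR172 at -0.08 ± 0.14. The silencing list had 1 of 26 lower, CCGCCTTGCACCAAGTGAAT of miR168 (-1.55 ± 0.33), also adjusted over the list alone, with the miR168 total at -0.67 ± 0.30. The 21 nt sequences had 1 of 238 higher and 12 lower (2 and 12 adjusted over the list alone). That list was lower by camera (adjusted p = 0.0315, and adjusted p = 0.199 with an estimated correlation) and by fry (adjusted p = 0.0283). The 22 nt sequences had 2 of 95 lower, ACCGGCGCTGCACGCAATGACG and GGCAAGTCCGTCCTTGGCTACA, also adjusted over the list alone. The 24 nt sequences had 0 of 33 with edgeR (0 adjusted over the list alone, 1 unadjusted, 1 by DESeq2). The count of called sequences was 49 without control 3 h replicate 1, which lay apart on the first principal component, 9, 14 and 13 without heat 3 h replicates 1, 2 and 3, and 13 and 18 without control replicates 2 and 3. It was 58 with DESeq2, 55 with no filter and 66 in the fit of all 18 libraries, where miR528 missed the threshold (adjusted p = 0.0551, range over its alternatives 2.99e-07 to 0.0551).

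At 6 h, within 1 lane, 12 of 75 families passed, 7 higher and 5 lower. miR444 fell from 40860 ± 558 CPM in control to 21164 ± 500 CPM in heat (-0.95 ± 0.09, adjusted p = 0.000809). miR399 and miR827, which act in phosphate homeostasis, fell from 1884 ± 685 to 704 ± 179 CPM (-1.42 ± 0.34, adjusted p = 0.0312) and from 2678 ± 783 to 1131 ± 90.7 CPM (-1.24 ± 0.26, adjusted p = 0.0227). miR172, which targets AP2-like transcription factor mRNAs, rose from 41.6 ± 6.65 to 98.6 ± 22.8 CPM (1.24 ± 0.26, adjusted p = 0.0227), and miR319, which targets TCP transcription factor mRNAs, from 12697 ± 1998 to 20688 ± 3214 CPM (0.70 ± 0.17, adjusted p = 0.0312). miR9863, a family that targets Mla immune receptor mRNAs in barley, rose from 32.9 ± 3.74 to 73.2 ± 12.2 CPM (1.15 ± 0.23, adjusted p = 0.0227).

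The other called families at 6 h were miR165 (1.53 ± 0.32, adjusted p = 0.0227), miR5051 (1.01 ± 0.22, adjusted p = 0.0227), miR5083 (0.75 ± 0.20, adjusted p = 0.0463) and miR167 (0.42 ± 0.11, adjusted p = 0.038), all higher, and miR5200 (-1.38 ± 0.36, adjusted p = 0.038) and miR166 (-0.28 ± 0.06, adjusted p = 0.0227), both lower. miR5200 is known in a related grass for targeting flowering-time FT mRNAs. All 12 totals differed in the same direction in each heat library against every control, 17 families were under an unadjusted p of 0.05, and DESeq2 called 12. Of the sequences 82 of 675 passed, 41 higher and 41 lower, in 27 families, and ranges did not overlap for 33.2% of the 675 against 10% by chance. By annotation 58 of the 82 were precursor sequences and 24 mature arms. AGAGCGTCCTTCAGTCCACT (3.50 ± 0.52, adjusted p = 0.00402) and CTTGGACTGAAGGGTGCTCC (3.36 ± 0.38, adjusted p = 0.00158), both of MIR319b, rose most among called sequences with a mean of at least 10 CPM and no overlap of ranges, the latter from 7.61 ± 3.07 to 78.8 ± 22.4 CPM. TGAGAAGGTAGATCATAATAGC, the mature 3′ sequence of MIR9863a and MIR9863b, CAGGCTTTCTTGAACTGTC of MIR396 and GGCGGTCACCTTGGCTAG of MIR169c rose by 3.06 ± 0.55, 3.00 ± 0.56 and 2.05 ± 0.42, with adjusted p from 0.0117 to 0.0159. CCTAGTTCTCTTCTTCTGGTG of MIR169c fell from 203 ± 19.7 to 25.6 ± 9.40 CPM (-2.99 ± 0.29, adjusted p = 0.00124), and GAATGACGCCGGGTCCGAAAG of MIR166b from 356 ± 120 to 65.7 ± 21.7 CPM (-2.43 ± 0.31, adjusted p = 0.0026). GTGCAGTTCTCCTCTGGCATG of MIR399a (-2.67 ± 0.64), CCTGTGCCTGCCTCTTCCATT of MIR528 (-2.64 ± 0.58) and CAGGGATGGAGCAGAGCAAGG of MIR408 (-2.48 ± 0.49) also fell, with adjusted p from 0.0136 to 0.0282. These 3 calls were lost in 4, 3 and 2 of 13 alternatives, that of GGCGGTCACCTTGGCTAG in 4, and those of CAGGCTTTCTTGAACTGTC and TGAGAAGGTAGATCATAATAGC in 1 each. TTCGGACCAGGCTTCATTCCC stood at 279092 ± 1651 against 338990 ± 22260 CPM (-0.28 ± 0.10, adjusted p = 0.105).

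Among the families of earlier barley heat work, miR167 rose, miR166 fell, miR160 stood at 0.30 ± 0.18 (adjusted p = 0.396) and miR5175 had 0 and 3 counts. The call was lost in 9 of 11 alternatives for miR166, which stood at -0.01 with implied library totals (adjusted p = 0.979, range over its alternatives 0.0282 to 0.979). Of the same 11 alternatives the call was lost in 8 for miR167 and miR5200, 6 for miR319 and miR5083, 5 for miR399, miR827, miR172, miR9863 and miR5051, 4 for miR165 and 1 for miR444. Of their 109 sequences 8 rose and 5 fell, as many adjusted over the list alone. The phosphate and sulfate list had 2 of 3 families lower and 4 of 14 sequences lower (6 adjusted over the list alone). Among them was the mature miR827 sequence TTTTGTTGGTTGTCATCTAACC (-1.69 ± 0.25, adjusted p = 0.00395), named with TTTTGTTGGTTGTCATCT and TGCCAAAGGAGAGTTGCCCTG after their values were seen. The other was GTGCAGTTCTCCTCTGGCATG, and miR395 stood at 0.35 ± 0.34. Its camera adjusted p was 0.0022 (adjusted p = 0.449 with an estimated correlation). The leaf development list had 2 families higher (miR165, miR319) and 1 lower (miR166) of 5. Adjusted over the list alone 3 were higher and 1 lower, the added one being miR396 at 0.26 ± 0.09, and miR159 stood at -0.34 ± 0.25. Of its 178 sequences 20 rose and 6 fell (20 and 8 adjusted over the list alone). Camera put it above the other sequences (adjusted p = 0.00449, and adjusted p = 0.449 with an estimated correlation). The NF-YA and GRAS regulators had 1 of 87 sequences higher, GGCGGTCACCTTGGCTAG, and 14 lower (1 and 16 adjusted over the list alone), 12 of them miR169 and 2 miR171. Its camera adjusted p was 0.0022 (adjusted p = 0.449 with an estimated correlation). The totals of miR169 and miR171 stood at -0.15 ± 0.16 and -0.36 ± 0.17.

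The auxin list at 6 h had 1 of 5 families higher, miR167, and 6 of 70 sequences higher with 1 lower, CTGGCTCCCTGAATGCCATCC of MIR160f (4 and 1 adjusted over the list alone). There miR393 stood at -0.08 ± 0.15 and miR390 at 0.16 ± 0.21. The phase change list had miR172 higher of 2 families, with miR156, which targets SPL transcription factor mRNAs, at -0.15 ± 0.22. By sequence 0 of its 41 sequences passed with edgeR (0 adjusted over the list alone, 8 unadjusted, 4 by DESeq2). The copper list had 2 of 27 sequences lower, those of MIR408 and MIR528 above, as many adjusted over the list alone. Of its 4 families 0 passed with edgeR (0 unadjusted, 0 by DESeq2), with miR408 at -0.03 ± 0.37, miR397 at -0.19 ± 0.24, miR528 at -0.14 ± 0.46 and miR398 at 0.14 ± 0.33. The silencing list had 3 of 25 sequences higher and 1 lower (6 and 4 adjusted over the list alone), all miR168, whose total stood at -0.08 ± 0.16. The cereal list had 1 of 16 families higher (miR5051) and 2 lower (miR444, miR827), by both counts. Of its sequences 5 of 110 were higher and 11 lower, as many adjusted over the list alone, with miR5048 at -0.18 ± 0.18. The 21 nt sequences had 9 of 232 higher and 22 lower (10 and 25 adjusted over the list alone), and the 22 nt sequences 5 of 94 higher and 4 lower (4 and 4). The 24 nt sequences had 1 of 30 lower, ATCTCGGACCAGGCTTCAATCCCT of MIR5168 (0 adjusted over the list alone), with a camera adjusted p of 0.00941 for lower levels (adjusted p = 0.667 with an estimated correlation). Fry called 0 of the 12 lists at 6 h. Without control 6 h replicates 1, 2 and 3 the called sequences numbered 23, 25 and 47 and the families 1, 1 and 3, while without heat replicates 1, 2 and 3 there were 54, 75 and 66 sequences and 2, 8 and 5 families. With implied library totals miR165, miR172 and miR9863 alone passed among families, and miR444 stood at -0.67 (adjusted p = 0.225, range over its alternatives 2.72e-11 to 0.225), the only alternative in which it missed the threshold at 6 h.

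**Figure D1:**
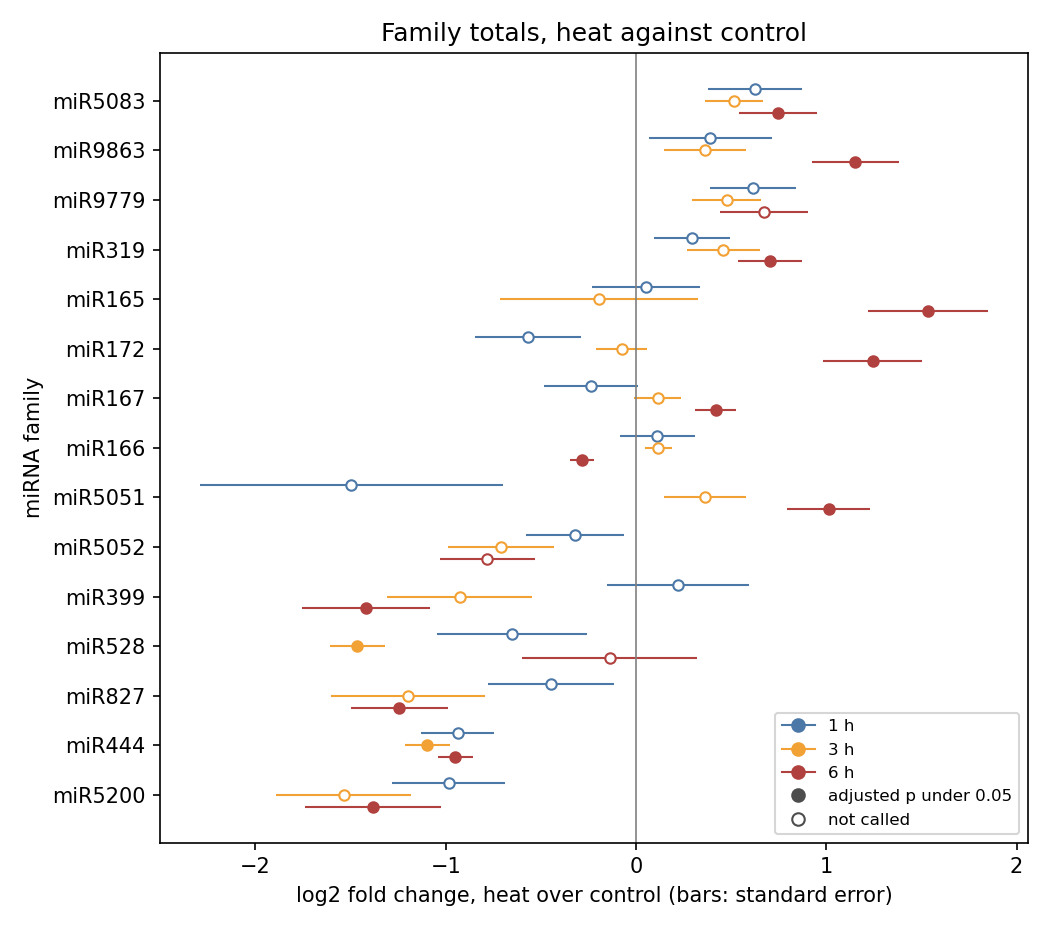
Log2 fold change of heat over control (horizontal axis) for the 15 miRNA families called at any time or on average, with 1, 3 and 6 h in separate colours, bars for the standard error and filled points for an adjusted p under 0.05 in the test of that time. miR444 lies at -0.94, -1.10 and -0.95 at 1, 3 and 6 h, and the heat and control libraries of 3 h lay on different lanes.

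Calls were shared between times in the same direction. The expected numbers treat sequences as independent, which overlapping forms of 1 precursor are not, so they are a rough guide only. Of the sequences tested in both tables, 8 fell at both 1 h and 3 h where independent lists of these sizes would share 0.313, 9 fell at both 1 h and 6 h against 0.555, and 15 fell at both 3 h and 6 h against 1.42. Shared rises numbered 0 against 0.021, 1 against 0.117 (the MIR444b sequence TGCAGTTGCTGCCTCAAGCTT) and 5 against 0.41, and 0 sequences were called in opposite directions. The 8 sequences lower at all 3 times were CGGCAAGCTAGAGACAGCAAC, GGCAAGCTAGAGACAGCAAC, GCAAGCTAGAGACAGCAAC and CAAGCTAGAGACAGCAAC of MIR444c, CCTAGTTCTCTTCTTCTGGTG and CCTAGTTCTCTTCTTCTGGT of MIR169c, GAATGACGCCGGGTCCGAAAG of MIR166b and AGCTGCCGACTCATTCATCC of MIR319a and MIR319b. The authors' deposited tables list 15, 34 and 66 sequences at an FDR under 0.05 at 1, 3 and 6 h, of which 13, 26 and 53 were also called here, all with the same sign.

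**Figure D2:**
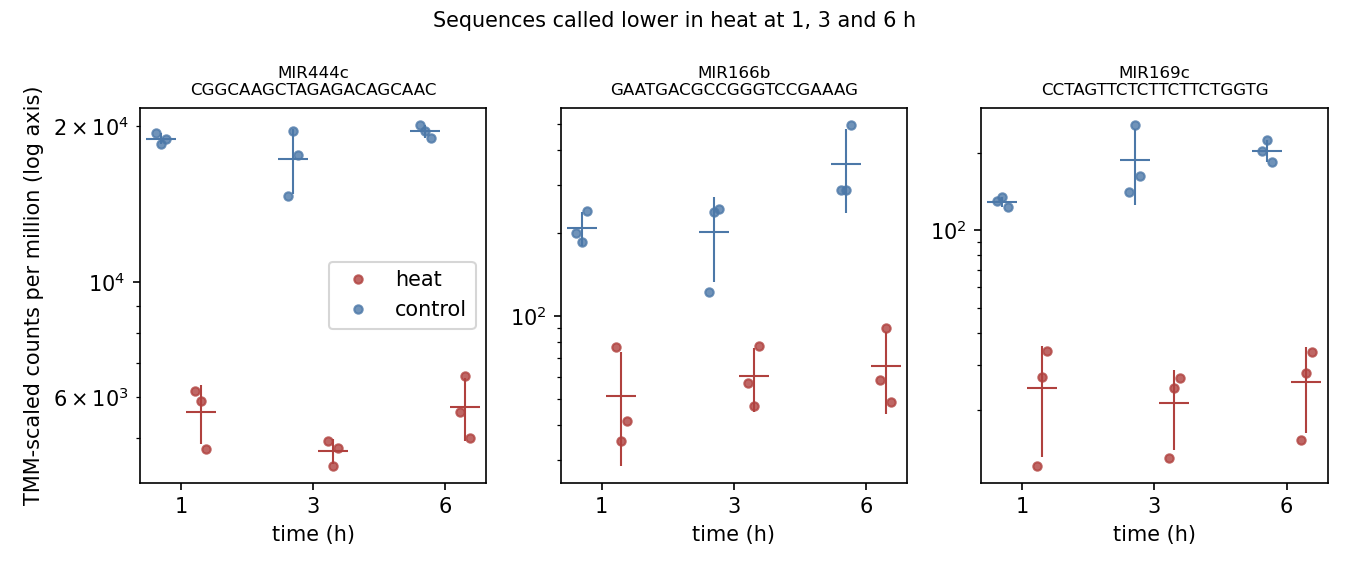
Scaled CPM (log axis) of 3 sequences of MIR444c, MIR166b and MIR169c in each of the 18 libraries by hours of exposure, heat and control in separate colours, with a horizontal mark for the mean and a bar for the SD. Each time was scaled on its own; every heat library lies below every control library of its time, for example 5617 against 18935 CPM on average for the MIR444c sequence at 1 h.

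The average of the 3 heat effects, fitted over all 18 libraries, asks which miRNAs differ in the mean over the durations. A large effect at 1 duration can be enough to pass. In the fits of each time alone, miR528 stood at -0.65, -1.46 and -0.14 at 1, 3 and 6 h and was called at 3 h only. miR444 fell by 0.98 ± 0.08 on the log2 scale (adjusted p = 9.71e-08), miR5200 by 1.33 ± 0.18 (adjusted p = 6.42e-05), miR827 by 0.94 ± 0.21 (adjusted p = 0.0048), miR528 by 0.75 ± 0.24 (adjusted p = 0.0488) and miR5052 by 0.53 ± 0.16 (adjusted p = 0.042). miR5083 rose by 0.65 ± 0.12 (adjusted p = 0.0018), miR9863 by 0.64 ± 0.16 (adjusted p = 0.013), miR9779 by 0.60 ± 0.13 (adjusted p = 0.00369) and miR319 by 0.50 ± 0.11 (adjusted p = 0.00516). These were 9 of 75 families, beside 145 of 961 sequences, 68 higher and 77 lower. With the libraries of 1 h and 6 h only, each within 1 lane, 8 families and 85 sequences passed, and miR528 (-0.42, adjusted p = 0.555, range over its alternatives 0.015 to 0.555) and miR5052 (-0.55, adjusted p = 0.069, range 0.0176 to 0.119) were lost. Over all 23 alternatives miR528 was lost in 14 and miR5052 in 11, and the other 7 families in 0. Without both libraries that stood apart on the first principal component, an alternative chosen after seeing the data, 13 families and 155 sequences passed.

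Whether the heat effect differs with duration was tested as the effect at 6 h minus that at 1 h, each within 1 lane. miR172 differed by 2.01 ± 0.33 on the log2 scale (adjusted p = 0.0009), with -0.57 ± 0.28 at 1 h and 1.24 ± 0.26 at 6 h in the fits of each time alone, and was the 1 called family of 75 (8 unadjusted, 2 by DESeq2, which added miR167). miR5051 and miR167 stood at 2.65 ± 0.85 and 0.79 ± 0.26, each with an adjusted p of 0.175. miR5051 passed as well without heat 1 h replicate 2, and miR166 without heat 1 h replicate 1. None of 961 sequences passed with edgeR, with 84 under an unadjusted p of 0.05 and 5 by DESeq2, and 9 passed without heat 1 h replicate 2. The other families called at 6 h and not at 1 h did not pass this test either, for example miR827 at -0.67 ± 0.51 (adjusted p = 0.94) and miR399 at -1.51 ± 0.56 (adjusted p = 0.202). The contrast per family was added after the data were seen. Time contrasts within a lane called 0 of 961 sequences with edgeR, both for heat at 3 h against 1 h (62 unadjusted) and for control at 6 h against 3 h (57 unadjusted), and DESeq2 was not run for them.

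The share of counts by sequence length showed the same dominant size in all groups, 21 nt, the usual length of plant miRNAs. At 6 h it was 80.2 ± 0.592% in heat and 83.2 ± 0.318% in control, a difference of -2.97 points that left no overlap between libraries (exact two-sided permutation p = 0.1, adjusted 0.5 over 15 tests). The shares of 20 nt (7.14 ± 0.221% against 5.98 ± 0.142%) and 22 nt sequences (7.95 ± 0.189% against 6.18 ± 0.242%) were higher in each heat library than in any control at 6 h, each with an exact p of 0.1. At 1 h and 3 h the 21 nt share differed by -0.31 and -1.41 points (exact p = 0.8 and 0.2). Without the 10 most abundant sequences the 21 nt differences were -5.40, -9.34 and -4.66 points at 1, 3 and 6 h. The difference in both mature arms together went from -0.35 to 0.99 points at 1 h, from 1.55 to -6.20 at 3 h and from 3.74 to 2.17 at 6 h. The smallest p that 3 libraries against 3 can give is 0.1, so no share could pass. Sequences annotated as a mature 5′ arm took 42.7 ± 2.80% of counts in heat and 38.4 ± 1.63% in control at 6 h, mature 3′ arms 10.8 ± 0.322% against 11.4 ± 0.154%, and other precursor positions 46.5 ± 2.74% against 50.2 ± 1.54% (each exact p = 0.1, adjusted 0.225 over 9 tests). The mature 5′ share was 45.6 ± 3.52% against 41.6 ± 3.23% at 3 h (exact p = 0.2) and 49.2 ± 2.33% against 49.3 ± 1.18% at 1 h (exact p = 1), and the mature 3′ share 9.15 ± 1.36% against 11.6 ± 0.833% at 3 h (exact p = 0.1). The annotated share of the implied library total was 6.33 ± 0.956% against 7.30 ± 0.817% at 1 h, 7.41 ± 0.758% against 6.06 ± 0.788% at 3 h and 7.25 ± 1.98% against 6.31 ± 0.228% at 6 h (exact p = 0.4, 0.2 and 0.5).

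**Figure D3:**
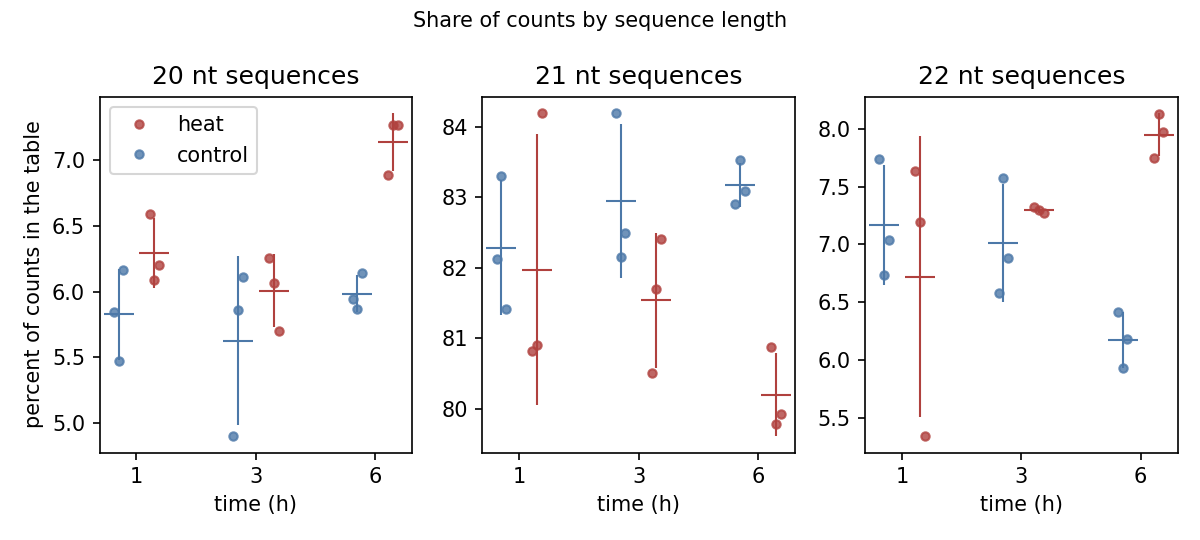
Percent of counts in sequences of 20, 21 and 22 nt in each library by hours of exposure, heat and control in separate colours, with a horizontal mark for the mean and a bar for the SD. At 6 h the 21 nt share averages 80.2% in heat and 83.2% in control.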

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

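All results in this part were picked out by a difference between times in the heat effect, and the contrasts of 6 h with 3 h were chosen only after the values at each time were seen. Groups of 3 libraries were not tested for a single library far from the others.

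miR172 was picked out by the test of the heat effect at 6 h minus that at 1 h, 2.01 ± 0.33 on the log2 scale (n = 3 libraries per group, edgeR adjusted p = 0.0009). Fitted alone, the effect was -0.57 at 1 h and 1.24 at 6 h, each within 1 lane. The family passed in all 15 alternatives for this contrast, with values of 1.73 to 2.14 and adjusted p from 5.93e-08 to 0.0102. Its level was low, at most 98.6 CPM on average in any group of either time, with each time scaled on its own. No technical or biological explanation was tested.

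miR166 was picked out because its libraries moved in opposite directions: each heat library lay above every control at 3 h (0.12) and below every control at 6 h (-0.28). The difference of 6 h minus 3 h was -0.39 ± 0.20 (edgeR adjusted p = 0.552), so no difference was shown. The most abundant miR166 sequence, TTCGGACCAGGCTTCATTCCC, was picked out for the same reason, with 0.12 at 3 h and -0.28 at 6 h and a difference of -0.39 ± 0.25 (edgeR adjusted p = 0.693). The values of 3 h carry the lane as well as the temperature.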

How the results depend on the processing

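The called families, and the called sequences named for the largest rises and falls, kept their direction under every alternative that gave a value. For the other called sequences the direction was not compared across alternatives. Counts that moved by more than 1.5 times are given with their setting, and where no reason follows, the cause was not tested. Scaling by implied library totals was chosen after seeing the data. No paired analysis was possible because the replicate numbers follow the order of the samples only and no pairing is given in the sources used here. Scaling over miRNA-annotated sequences and totals without mismatched sequences were not run, since every sequence was annotated with 0 mismatches, and pseudocounts do not apply to counts.

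With DESeq2 the called sequences were 23 at 1 h, 58 at 3 h and 5 for 6 h minus 1 h, against 13, 31 and 0, and the families 2, 5 and 2, against 0, 2 and 1. With no filter there were 28 sequences at 1 h, 55 at 3 h, 2 for 6 h minus 1 h and 1 for heat at 3 h against 1 h. The fit of all 18 libraries gave 66 sequences at 3 h. At 1 h it called 1 family, as did RLE factors and implied library totals, miR444 in each. With implied library totals 3 families passed at 6 h against 12. The average effect called 85 sequences with 1 h and 6 h only, against 145. That fit left out the libraries of 3 h, so fewer libraries, the effect at 3 h and its lane cannot be told apart as reasons.

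Leaving out 1 library at a time gave 11 to 23 sequences and 0 to 1 family at 1 h, 9 to 49 sequences and 2 to 3 families at 3 h, and 23 to 75 sequences and 1 to 8 families at 6 h. For 6 h minus 1 h it gave 0 to 9 sequences and 1 to 2 families, and for the average 124 to 155 sequences and 7 to 12 families. These fits hold fewer libraries, which lowers power, but the rise to 49 without control 3 h replicate 1 and to 23 without heat 1 h replicate 2 has no tested cause.

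For lists, camera with an estimated correlation called 0 at 3 h and 0 at 6 h, and fry called 3 and 0, against 5 and 4. Without the top 10 sequences the size class shares: 21 nt, heat minus control at 1 h, were -5.40 points against -0.31. The size class shares: 21 nt, heat minus control at 3 h, were -9.34 against -1.41, and the size class shares: 21 nt, heat minus control at 6 h, -4.66 against -2.97. The annotation class shares: mature arms, heat minus control at 3 h, were -6.20 against 1.55. For mature arms the difference at 1 h was 0.99 against -0.35, and at 6 h 2.17 against 3.74. The cause was not tested.

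Implied library totals moved the median sequence by -0.24 at 1 h and 0.25 at 6 h, and library size scaling by -0.20 at 3 h, which is why families near 0 turned sign there. Of the values of named features under the alternatives, 715 kept their direction and their side of the threshold, 128 lost the call and 13, none of them called, changed sign. Depth limits the rarest sequences, since the floor of 3 counts is up to 0.129 RPM.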

Other observations

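The tests of the 3′ ends, of miR444 and of the lane were written before their results, except that the one on well-counted pairs was chosen only after the result was seen. The rules for reading the RNA degradation and miR444 tests were tightened after their first values were seen.

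At 6 h forms of miR168, chosen after their values were seen, went in different directions while the mature sequence did not pass. CCCGCCTTGCACCAAGTGAA rose from 297 ± 21.9 to 811 ± 78 CPM (1.45 ± 0.15, edgeR adjusted p = 0.00132) and TCGCTTGGTGCAGATCGGGACC from 622 ± 11.6 to 1349 ± 161 CPM (1.12 ± 0.14, adjusted p = 0.0026). CCGCCTTGCACCAAGTGAAT fell from 974 ± 90.8 to 469 ± 41.6 CPM (-1.06 ± 0.15, adjusted p = 0.00343). The mature TCGCTTGGTGCAGATCGGGAC stood at -0.13 ± 0.19 (adjusted p = 0.709).

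The first pattern weighed is a shift of 3′ ends: over 257 pairs of sequences that differ by 1 nt at the 3′ end, the median log2 ratio of the shorter to the longer form was higher in heat by 0.146 on average over the times (exact stratified permutation p = 0.0188). The shift was -0.000773 at 1 h, 0.133 at 3 h and 0.305 at 6 h (exact p = 1, 0.1 and 0.1). Over the 63 pairs with a mean of at least 100 counts it was 0.0283 on average (exact permutation p = 0.82), with -0.174 at 1 h, 0.244 at 3 h and 0.0143 at 6 h. Low counts may therefore account for the shift, and 3′ shortening is left as a candidate explanation that the well-counted pairs did not show on average. Pairs differing at the 5′ end shifted by -0.0425 at 1 h, -0.0414 at 3 h, 0.153 at 6 h and 0.0229 on average (exact permutation p = 0.7, 0.9, 0.1 and 0.695). The 3′ shift exceeded theirs by 0.123 on average with an exact p of 0.0725, so RNA degradation stays possible.

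The second pattern is the lower miR444 total, with an average effect of -0.98. Without the MIR444c sequence CGGCAAGCTAGAGACAGCAAC and those that overlap it, the average effect was -0.507 ± 0.10 (edgeR adjusted p = 0.00384), with -0.41 at 1 h (adjusted p = 0.557), -0.69 at 3 h (adjusted p = 0.116, where the family call was lost) and -0.46 at 6 h (adjusted p = 0.0411). This met its bound of 0.5 times the reported effect by less than its SE, so how far that sequence sets the total stays open. The effect with implied library totals was -0.957 (adjusted p = 4.75e-05), so scaling over annotated sequences is unlikely to be the whole cause. No biological explanation was tested.

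The third pattern is the lane at 3 h. Of the 31 sequences called at 3 h, 30 had the same sign in the average of 1 h and 6 h, which lie within a lane, so lane is unlikely to be the whole cause for the set. For the 6 called sequences of miR397, miR408 and miR528 the median of that average was -1.10, with 5 of 6 lower, against a median fall of 3.09 at 3 h. In the groups of 1 h against those of 6 h, which mix lane 1 against lane 2 with time, 18 of the 31 had the sign of the 3 h effect (signed median 0.132), but 1 of these 6 (signed median -0.502). Whether lane plays a part in these 6 stays open.

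Other groupings of the libraries gave these counts. With 10 splits per time, too few for a share under 0.05, the real grouping called 13 sequences at 1 h (1 of 10 splits as large, highest other 1), 31 at 3 h (1 of 10, highest other 0) and 82 at 6 h (1 of 10, highest other 0). For families these were 0 (10 of 10, highest other 0), 2 (1 of 10, highest other 0) and 12 (1 of 10, highest other 0). For lists they were 0 (10 of 10, highest other 5), 5 (4 of 10, highest other 6) and 4 (5 of 10, highest other 6), so other splits called as many lists. Time within a lane gave 0 (10 of 10) for heat, highest other 1, and 0 (10 of 10) for control, highest other 0.

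With 100 regroupings chance can be excluded for the average effect, with 145 sequences (1 of 100 as large, highest other 10) and 9 families (1 of 100, highest other 2). For 6 h minus 1 h, 1 family was called (4 of 100 as large, highest other 7), a share so near 0.05 in drawn regroupings that chance is not firmly excluded. For sequences 0 were called, so all 100 of 100 are as large by construction (highest other 78) and chance was not tested. The regrouping with 78 sequences is also the one with 7 families. It swaps heat and control completely at 1 h, so both of its counts measure the effect that both times share.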
